A study of Mus musculus with 9 samples.

How the data were processed

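Gene expression was measured on 1-colour short-oligonucleotide arrays in total RNA from OB-6 cells, a mouse osteoblastic line derived from bone marrow, at 0, 30 and 60 min of treatment with parathyroid hormone (PTH), with 3 arrays per time and 9 in all. The deposited table holds 1 intensity per probe set and array for 12488 probe sets. These intensities are linear and run from 0.1 to 8605.242. The summary method and the software with which the authors made them are not given in the sources used here. With 2% of the probe sets taken off each end, every array has a mean intensity of 250.1 or 250.2, so the deposited table was taken as already scaled between arrays and used as it stands, by a rule that allowed the trimmed means to differ by less than 1.1 times. The dose of PTH and the culture conditions are not given in the sources used here either. The labels do not say whether the 3 replicates of a time came from separate cultures, so all p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision.

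Gene names came from the platform annotation of the probe sets, in which 10833 probe sets had 1 gene symbol, 396 had several and 1193 had none. The mouse gene table of assembly GRCm38.p6 held the Entrez identifier of 10817 probe sets and changed 0 symbols. No gene was named from a probe set with several symbols. No coordinates are given, because the array data name no genome build for the probe sets.

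The intensities were converted to log2(intensity + 11.8), the added constant being the 20th percentile of all values. Fold changes are on this scale, which understates the change of dim probe sets. A probe set was tested if at least 3 of the 9 arrays lay above the 40th percentile of all values, an intensity of 44.69, and the 66 control probe sets were left out, which left 7884 probe sets. One linear model with a mean per time was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, 6 residual degrees of freedom and a prior of 4.68). Each pair of times was compared with limma's moderated test, and any change over the 3 times with its F test over both differences from 0 min. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05. With 3 arrays against 3, an exact permutation test of a single probe set cannot give a p under 0.1.

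For gene lists, each gene was represented by its probe set with the highest mean over all arrays, which gave 5936 genes. The 20 lists were written before the data were examined and hold 470 gene names, of which 381 have a probe set. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 18 lists tested, and again with an estimated correlation and with fry.

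The genes named were also chosen by a rule written before the data were examined. For each comparison with 0 min these were the 10 largest rises and the 10 largest falls among probe sets with 1 symbol that passed the threshold and whose 3 arrays at one time all lay above or all below the 3 at the other. For 60 against 30 min it was the 5 largest each way. From each list came up to 4 members past the threshold with the largest change, or the 2 brightest members where none passed, and a fixed panel of PTH and cAMP response genes was always given. A gene with several probe sets is described by the brightest, and disagreement is stated. The rule took 93 genes.

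The fit was tested on simulated arrays drawn from the real means and spreads of the 7884 probe sets, with 200 of them changed at 60 min in each of 10 draws. For 60 against 0 min it recovered 19.9% of changes of 0.5 on the log2 scale, 75.2% of changes of 1 and 98.3% of changes of 2, and 5.16% of its calls were false. The noise was drawn independently for each probe set, whereas 38.7% of the real variance within groups lay on 1 array-wide axis. These shares therefore may not carry over to the real arrays. Alternatives to each choice, including other constants, filters and scalings, the replicate letter as a block and each array left out in turn, were listed before the data were examined. Cyclic loess and a covariate for an array-wide axis, scored from probe sets without a clear time effect or from all tested ones, were added after seeing the data. Random gene lists numbered 10000 and were matched on mean signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.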

Results

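Expression was profiled in OB-6 osteoblastic cells before and after 30 or 60 min of parathyroid hormone, the hormone that acts on osteoblasts largely through a receptor coupled to cAMP signalling. Each time was represented by 3 arrays, named replicates a, b and c. The comparison addressed which genes PTH regulates within the first hour. Cultures handled for 30 or 60 min without PTH were not analysed here, so each change is given against the start of treatment. Correlations between arrays over the tested probe sets lay between 0.891 and 0.98. The array 60 min replicate b stood furthest from the rest, with a median correlation of 0.938 to the other arrays, against 0.954 to 0.967 for the remaining 8.

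After 30 min of PTH the 10 largest rises included 6 genes of the lists for immediate-early and cAMP-responsive genes. Fold changes here and below are on the log2(intensity + 11.8) scale. Fos, a subunit of the AP-1 transcription factor, rose 16.6-fold, from an intensity of 30.9 ± 3.45 to 698 ± 104 (SD, n = 3 arrays each), a log2 fold change of 4.05 with a standard error (SE) of 0.19 and a limma adjusted p of 3.44e-06. Egr1, a zinc finger transcription factor, rose 6.66-fold from 98.8 ± 9.38 to 727 ± 98.7, with a log2 fold change of 2.74 (SE 0.20, limma adjusted p = 9.61e-05). Nr4a1, an orphan nuclear receptor induced by cAMP, rose 5.87-fold from 44.0 ± 19.1 to 306 ± 46.8 (limma adjusted p = 0.000457). The matricellular protein gene Ccn2 rose 4.94-fold, Ier2 4.27-fold and Junb 2.95-fold. Dusp1, a phosphatase that switches off MAP kinases, was already bright and rose 3.51-fold from 623 ± 9.07 to 2221 ± 143 (limma adjusted p = 1.42e-05). Phlda1 rose 2.89-fold. For all 8 of these genes the call remained whichever of the 9 arrays was left out. Unc5c and Mc3r completed the 10 largest rises, from dim probe sets at 11.9 and 31.0. The call of Unc5c was lost without any 0 min array or 30 min replicate c, and that of Mc3r without 0 min replicates a or c, any 30 min array or 60 min replicate c.

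**Figure D1:**
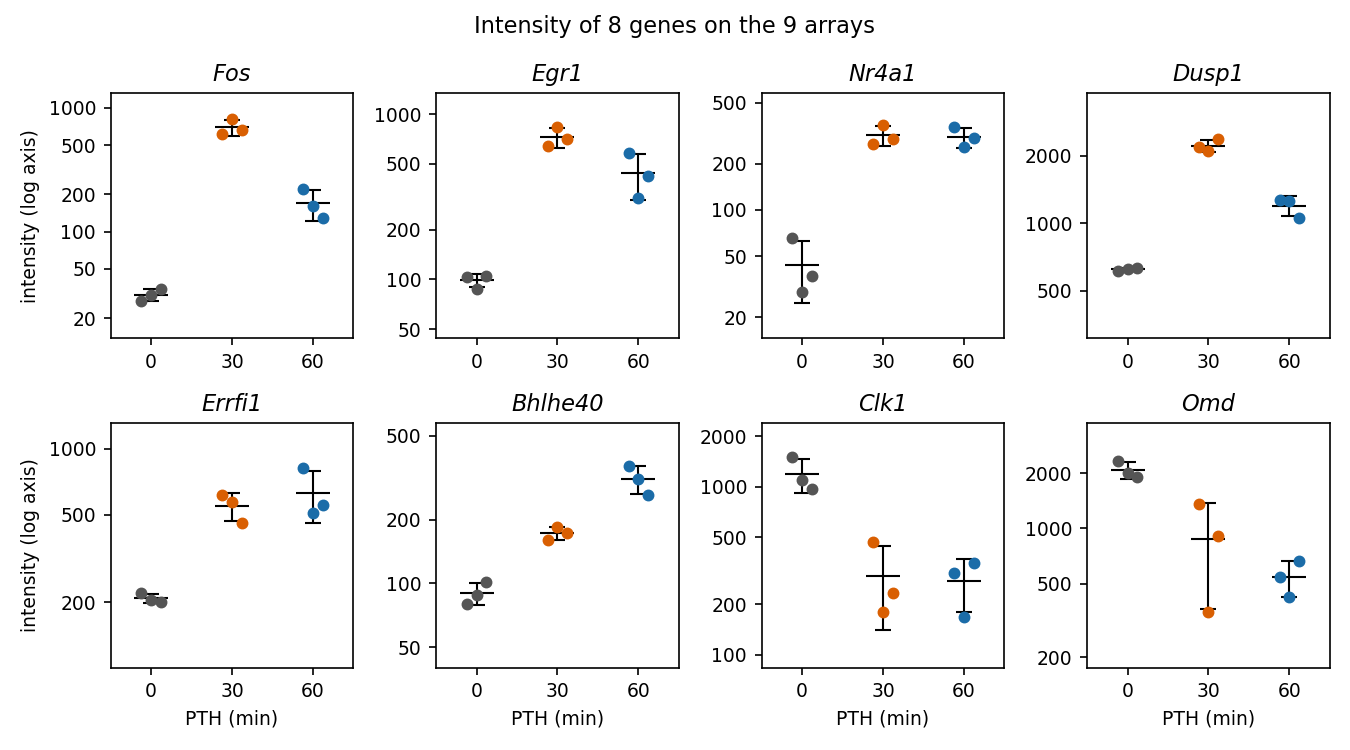
Intensity (log axis, arbitrary units) of 8 genes at 0, 30 and 60 min of PTH. Points are single arrays, horizontal bars the mean of 3 arrays and whiskers 1 SD. Fos stood at 30.9 at 0 min, 698 at 30 min and 169 at 60 min, while Bhlhe40 was highest at 60 min and Clk1 and Omd lay below their 0 min arrays at both later times.

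The largest falls at 30 min included those of Clk1 and Clk4, kinases that phosphorylate splicing factors, which fell by 2.06 (SE 0.34) and 1.90 (SE 0.25) on the log2 scale, to 293 ± 153 from 1184 ± 273 for Clk1 and to 42.6 ± 5.42 from 191 ± 13.8 for Clk4, with limma adjusted p of 0.0254 and 0.00678. Other genes that fell were Ssb, encoding the RNA-binding La protein, Cops2, a subunit of the COP9 signalosome, Smc4, a condensin subunit, Hnrnpu, a nuclear RNA-binding protein, Sh3bgrl, and the zinc finger genes Zfp943 and Zfp62, with log2 fold changes between -2.02 and -1.63. Probe sets of 1 gene did not always move together. One probe set of Rbmx, which encodes another nuclear RNA-binding protein, fell by 1.77 on the log2 scale, while its brightest probe set stood at -0.07 (SE 0.14). The second probe set of Clk4 stood at -1.10, with a limma adjusted p of 0.155, and that of Cops2 at -1.29, with 0.072. Every one of the 9 named falls lost its call without 0 min replicate a. Each but Clk4 lost it without 30 min replicates b or c, each but Hnrnpu without 0 min replicate b, and each but Clk4 without 0 min replicate c. Without 60 min replicate c the calls of Ssb, Cops2, Smc4, Sh3bgrl, Zfp943 and Zfp62 were lost, and that of Zfp943 also without 60 min replicate a.

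Among the lists at 30 min, the immediate-early transcription factors moved most. Of 22 measured members 8 rose and 0 fell, and 13 rose when adjusted over the list alone. The list stood above other genes with a camera adjusted p of 5.5e-13, and of 0.00529 with an estimated correlation. Feedback regulators of signalling had 4 of 17 members higher, among them Dusp6 with a log2 fold change of 1.07, the EGF receptor inhibitor Errfi1 with 1.34 and Socs1 with 0.68, and 5 when adjusted over the list alone. Its camera adjusted p was 0.000857, and 0.0712 with an estimated correlation. The estimate was 0.01, the preset value, so correlation between these genes was not the reason for the difference. Genes under cAMP and CREB control had 3 of 15 members higher, Nr4a1, Dusp1 and Bhlhe40, and 6 higher and 1 lower when adjusted over the list alone, with a camera adjusted p of 0.00249, and 0.229 with an estimated correlation. Known PTH targets had 3 of 19 higher, Fos, Junb and Nr4a1, and 3 when adjusted over the list alone, with a camera adjusted p of 0.015, and 0.405 with an estimated correlation. The 3 PTH targets that rose all stand in other lists as well, and the list's adjusted p was 0.051 without 0 min replicate c. The cell cycle list had 2 of 26 members higher, Mcm2 and Mcm3, both subunits of the replicative helicase, and 10 higher and 2 lower when adjusted over the list alone. Its camera adjusted p was 0.0383, and 0.642 with an estimated correlation. Without 0 min replicate b it was 0.106, without 30 min replicate a 0.736 and without a filter 0.0618, over a range of 0.000585 to 0.736 in the alternatives.

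Single members of other lists also passed the threshold at 30 min. Ccn2 and Hbegf, the latter with a log2 fold change of 0.80, were the 2 of 20 secreted factors that rose, Id1 with 0.62 and Ccn2 the 2 of 15 BMP and TGF-beta response genes, Plaur with 0.81 the 1 of 14 matrix protease genes, Ier3 with 1.39 the 1 of 15 NF-kappaB response genes, and Bhlhe40 with 0.87 the 1 of 15 clock genes. Sfrp2, a secreted Wnt modulator, fell by 0.79, the 1 of 15 Wnt pathway genes past the threshold. Adjusted over the list alone, 4 secreted factors were higher and 2 lower, 3 NF-kappaB and 2 clock genes higher, and the other counts of these lists were the same. The calls of Socs1, Id1, Mcm2, Bhlhe40, Plaur, Sfrp2, Hbegf and Mcm3 were each lost without any 0 min array and without 30 min replicate c, all but those of Hbegf and Mcm3 also without 30 min replicate b, and those of Socs1, Id1 and Mcm2 also without 60 min replicates a or c. No member passed in the lists for bone matrix (22 measured), Notch (9), heat shock (19), ribosomal proteins (12), adipocytes (6), haematopoietic cells and osteoclasts (7) or skeletal muscle (7), and camera adjusted p for these and the preceding lists of this paragraph lay between 0.174 and 0.988. Adjusted over the list alone, 1 bone matrix gene was higher and 2 were lower, 2 heat shock genes were higher and 1 lower, and 1 muscle gene was higher. Chondrocyte and endothelial markers, with 4 and 2 measured members, were not tested as lists and had 0 members past the threshold at either time. The brightest bone matrix genes, Col1a2 and Bgn, stood at log2 fold changes of -0.05 and 0.10.

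In all, 74 of 7884 probe sets changed at 30 min, 38 higher and 36 lower, from 35 and 31 genes, and 1412 had an unadjusted p under 0.05. The 3 arrays of one time lay wholly above or below those of the other for 30.6% of the probe sets, where chance gives 10% on average over splits. Deviations that many probe sets share on an array can move the share of a single split from 10%, so the excess is descriptive. The count depended on single arrays, chiefly through the falls. It was 16, 19 and 23 without 0 min replicates a, b and c, 307, 23 and 17 without 30 min replicates a, b and c, and 67, 557 and 37 without 60 min replicates a, b and c, with 15 to 166 rises and 1 to 391 falls. It was 389 in a fit of these 2 groups alone, and 52 rises and 93 falls after quantile normalization, 40 and 61 after scaling to the 75th percentile and 32 and 60 after cyclic loess.

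After 60 min of PTH, Nr4a1 was the gene with the largest rise, at 5.73-fold with an intensity of 298 ± 44.6 and a log2 fold change of 2.52 (SE 0.23, limma adjusted p = 0.000803). Fos stood at 169 ± 46.5, 4.16-fold above the start (log2 fold change 2.06, SE 0.19, limma adjusted p = 0.000803), and Egr1 at 439 ± 138, 3.96-fold above it. Bhlhe40, a transcriptional repressor of the clock, rose 3.17-fold from 89.8 ± 11.2 to 312 ± 48.0 (limma adjusted p = 0.000803). Ier2 rose 2.92-fold, Errfi1 2.84-fold, Junb 2.68-fold and Fosl1, a Fos-related AP-1 subunit, 2.51-fold. The calls of these 8 genes remained with any 1 array left out. Unc5c, from its dim probe set, rose 2.46-fold to 47.8 ± 14.3 (limma adjusted p = 0.0194), a call lost without any 0 min array or 60 min replicate b. Id1, an inhibitor of differentiation induced by BMP signalling, rose by a log2 fold change of 1.15 and Id3 by 0.91. The transcription factor genes Jun (0.82), Cebpd (0.86), Cebpb (0.50) and Msx2 (0.74) passed the threshold at 60 min and not at 30 min, where their log2 fold changes were 0.59, 0.60, 0.19 and 0.65. None of these 4 passed in the test of 60 against 30 min, with limma adjusted p between 0.54 and 0.836. The calls of Jun, Cebpb and Msx2 at 60 min were lost without any 0 min array, those of Cebpd and Id3 without 0 min replicates a or b, that of Jun also without 60 min replicate c and that of Cebpb without 60 min replicate b.

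Falls outnumbered rises at 60 min and were larger. The median log2 fold change of the 688 probe sets that fell was -1.05, against 0.56 for the 343 that rose. The risen ones were brighter, with a median of mean intensities of 737, against 208 for the fallen and 215 for all tested. Arrays at 60 min had lower median intensities than those at 0 min (73.06 to 80.25 against 82.31 to 85.92). Their 99th percentiles were higher (3852 to 4722 against 3474 to 3606). Ube2v2, a ubiquitin-conjugating enzyme variant, fell by 2.36 on the log2 scale (SE 0.41) from 140 ± 10.5 to 19.5 ± 11.3, and Ifi202b, an interferon-inducible gene, fell by 2.28 (SE 0.39) from 963 ± 108 to 198 ± 74.1, with limma adjusted p of 0.0096 and 0.00958. Cops2, Clk4, Clk1, Smc4, Zfp62 and Ssb had log2 fold changes between -2.23 and -1.93. The second probe set of Clk4 stood at -1.0 (limma adjusted p = 0.0841) and that of Cops2 at -1.98 (0.00733). Omd, a small proteoglycan of bone matrix, fell by 1.93 (SE 0.38) from 2083 ± 225 to 544 ± 120, with a limma adjusted p of 0.0145. Rbmx belonged to the 10 largest falls by its dimmer probe set, at -2.07, while its brightest stood at 0.02. Tnfrsf11b, encoding osteoprotegerin, the decoy receptor for RANKL, fell by 1.25 (SE 0.24) from 432 ± 48.9 to 183 ± 67.4 (limma adjusted p = 0.0144). The call of Tnfrsf11b was lost without any 0 min array, those of Omd and Ssb without 0 min replicates a or b, and those of Ube2v2, Ifi202b, Cops2, Clk1 and Zfp62 without 0 min replicate a. The fallen probe sets lay furthest from their 0 min mean on 60 min replicate b, by a median of -1.43, against -0.70 on replicate a and -0.91 on replicate c. Without that array their median log2 fold change was -0.82. At 30 min the same probe sets already stood at a median of -0.68, to which the shared 0 min arrays may contribute.

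**Figure D2:**
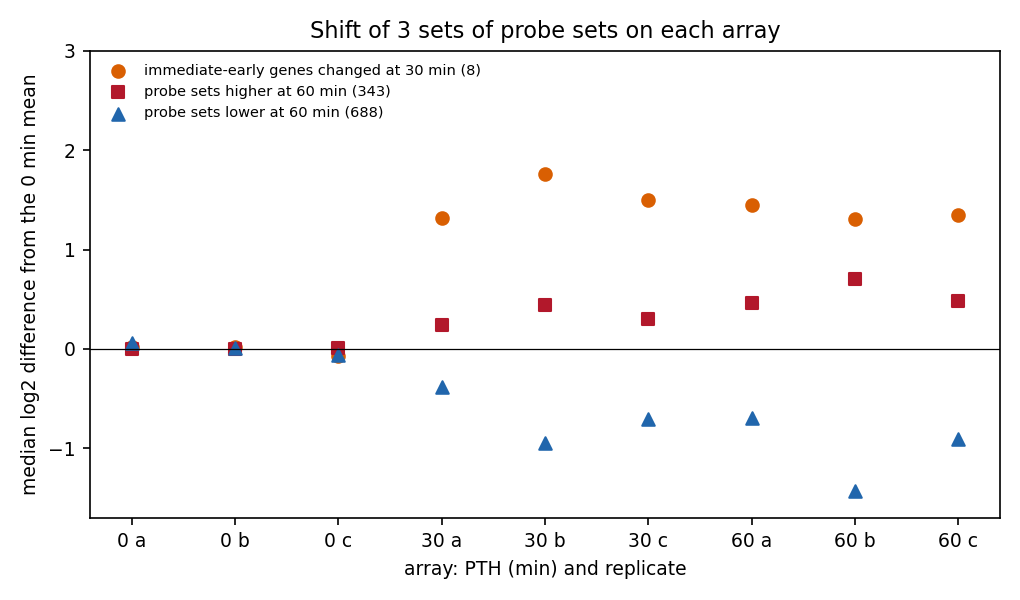
Median log2 difference from the 0 min mean on each array, for the 8 immediate-early genes that rose at 30 min (circles), the 343 probe sets higher at 60 min (squares) and the 688 lower at 60 min (triangles). The immediate-early genes stood between 1.31 and 1.76 on the 6 PTH arrays, and the fallen probe sets between -0.38 on 30 min replicate a and -1.43 on 60 min replicate b. The sets were chosen from these arrays, so their displacement from 0 is partly selection.

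The immediate-early list again led the lists at 60 min, with 10 of 22 members higher and 0 lower, and 13 higher and 1 lower when adjusted over the list alone. Its camera adjusted p was 5.79e-07, and 0.0288 with an estimated correlation. Genes under cAMP and CREB control had 6 of 15 members higher and 7 when adjusted over the list alone, with a camera adjusted p of 0.00387, and 0.347 with an estimated correlation. The NF-kappaB list had 5 of 15 higher, including the inhibitors Nfkbia (log2 fold change 0.48) and Nfkbib (0.54), Ier3 (1.07) and the chemokine gene Cxcl1 (0.47), and 8 higher and 1 lower when adjusted over the list alone. Its camera adjusted p was 0.0331, and 0.447 with an estimated correlation, and 0.166 after quantile normalization. It was 0.0584 without 0 min replicate c, 0.109 without 60 min replicate a and 0.0736 without 60 min replicate c, over a range of 0.00602 to 0.447 in the alternatives. A second probe set of Nfkbia stood at 0.14 (limma adjusted p = 0.425). The calls of Nfkbia, Nfkbib and Cxcl1 were lost without any 0 min array, those of Nfkbia and Nfkbib also without 60 min replicate c and that of Nfkbib without 60 min replicate b. That of Cxcl1 was lost after quantile normalization. Of 12 ribosomal protein genes 2 rose, Rps19 (0.79) and Rps24 (0.57), and 5 when adjusted over the list alone, with a camera adjusted p of 0.00621, and 0.471 with an estimated correlation. The median of that list was 0.28 as deposited, 0.35 after 75th percentile scaling, 0.09 after cyclic loess and 0.05 after quantile normalization, which ended the call at an adjusted p of 0.637. The calls of Rps19 and Rps24 were lost without any 0 min array, and that of Rps24 also after quantile normalization and without 30 min replicates b or c or 60 min replicates b or c.

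Other lists at 60 min held members that moved in both directions. Known PTH targets had 4 of 19 higher (Nr4a1, Fos, Junb and Cebpb) and 1 lower (Tnfrsf11b), with 6 and 2 when adjusted over the list alone and a camera adjusted p of 0.0954. This adjusted p was 0.00708 without 60 min replicate b and 0.0271 without 0 min replicate a, over a range of 0.00648 to 0.471 in the alternatives. Bone matrix and differentiation genes had 3 of 22 higher, including Msx2 and Col1a1 (0.56, limma adjusted p = 0.0499), and 2 lower, Omd and Postn (-1.23), with 5 and 6 when adjusted over the list alone and a camera adjusted p of 0.87. The median of the list was 0.12 and its mean -0.14, and the median turned to -0.04 after quantile normalization and -0.07 after cyclic loess. A second probe set of Col1a1 stood at 0.08, and the call was lost after quantile normalization and in 7 of the 9 fits with 1 array left out, all but those without 0 min replicate c or 60 min replicate a. The calls of Postn and Msx2 were lost without any 0 min array. Of 20 secreted factors 3 rose, with Ccn2 at 1.22 and Hbegf at 0.65, and 2 fell, Fgf7 (-1.07) and Inhba (-0.58), with 4 and 3 when adjusted over the list alone. The calls of Ccn2 and Hbegf were lost without 0 min replicates a or b. Feedback regulators had 5 of 17 higher and 1 lower, also when adjusted over the list alone, with a camera adjusted p of 0.154, and 0.0416 without 60 min replicate b, over a range of 0.00255 to 0.471 in the alternatives. The cell cycle list had 5 of 26 higher, led by Mcm2 (0.81) and with Mcm3 at 0.64, and 2 lower, Mki67 (-1.69) and Bub1 (-1.05), with 9 and 3 when adjusted over the list alone and a camera adjusted p of 0.0954, and 0.00209 without 60 min replicate b, over a range of 0.000631 to 0.769 in the alternatives. A second probe set of Mki67 stood at 0.03. Of the clock genes Bhlhe40 rose, and Nr1d2 (-1.34) and Clock (-1.18) fell, with 2 higher and 2 lower when adjusted over the list alone. The calls of Fgf7, Inhba, Mki67, Bub1, Nr1d2 and Clock were lost without any 0 min array, those of Inhba, Mki67 and Bub1 also without 60 min replicates b or c, that of Nr1d2 without 60 min replicate c, and those of Nr1d2 and Bub1 without 30 min replicate c. Those of Inhba and Bub1 were lost after quantile normalization.

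**Figure D3:**
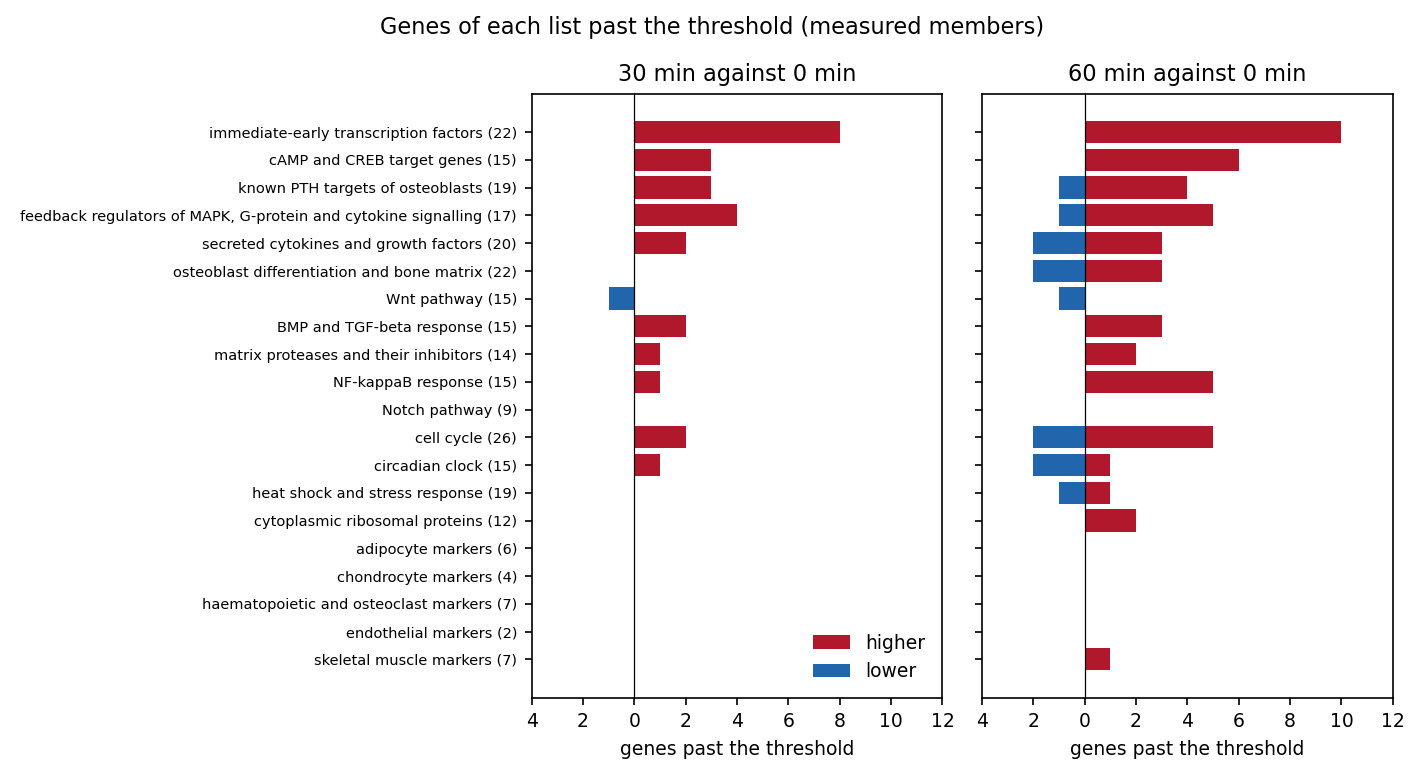
Number of genes past the threshold in each of the 20 lists at 30 min (left) and 60 min (right), with higher genes to the right of 0 and lower genes to the left, and measured members in brackets. The immediate-early list has the longest bars, with 8 genes at 30 min and 10 at 60 min of 22 measured.

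Few members of the remaining lists changed at 60 min. Dnajb1 (0.59) rose and Hsp90aa1 (-1.57) fell among 19 heat shock genes, Id1, Id3 and Ccn2 rose among 15 BMP and TGF-beta response genes, Timp1 (0.47) and Plaur (0.59) among 14 protease genes, and Sfrp2 fell by 0.51 among 15 Wnt genes. Adjusted over the list alone, 3 BMP and TGF-beta genes were higher, 3 protease genes higher and 1 lower, 1 heat shock gene higher and 1 lower, and 0 Wnt genes changed. The medians of these lists were close to 0, and the sign of the heat shock median (0.06), the Wnt median (-0.03), the clock median (-0.04) and the muscle median (-0.07) turned under at least 1 other scaling. The calls of Dnajb1, Hsp90aa1, Timp1, Plaur, Sfrp2 and Ckm were lost without any 0 min array, those of Timp1, Hsp90aa1 and Sfrp2 also without 60 min replicate b, that of Timp1 without 60 min replicate c and after quantile normalization, and that of Sfrp2 without 30 min replicate c or 60 min replicate a and after 75th percentile scaling. Of the markers of other cell types the brightest were Col11a1 for cartilage, with a log2 fold change of -0.82 (limma adjusted p = 0.0512), Cd14 for haematopoietic cells, at 0.27, and Cebpa for adipocytes, at 0.24, and Sox18 for endothelium, at -0.32, none of them past the threshold. The median of the 4 cartilage markers was -0.50, with 1 lower when adjusted over the list alone. Of 7 skeletal muscle markers 1, Ckm, rose (0.86) from a dim 53.4 ± 10.9, also when adjusted over the list alone. Without 60 min replicate b the BMP and TGF-beta list had a camera adjusted p of 0.0303, over a range of 0.0268 to 0.471 in the alternatives. Camera adjusted p lay between 0.154 and 0.954 for the lists of this paragraph that were tested, the Notch pathway, the secreted factors, the clock genes and the feedback regulators.

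At 60 min 1031 probe sets changed, 343 higher and 688 lower, from 293 and 574 genes, and 2589 had an unadjusted p under 0.05. Of these, 27 rises and 369 falls were at least 2-fold. The arrays did not overlap for 40.7% of the probe sets, where chance gives 10% on average over splits, with the same limit as at 30 min. The count was 77, 107 and 259 without 0 min replicates a, b and c, 1584, 528 and 646 without 60 min replicates a, b and c, and 692 to 1226 without a 30 min array. The 528 without 60 min replicate b were 155 rises and 373 falls, and 501 of them were among the 1031. Scaling to the 75th percentile gave 500 rises and 651 falls, quantile normalization 383 and 623, and cyclic loess 227 and 621.

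Between 30 and 60 min 2 probe sets changed, both lower, and 715 had an unadjusted p under 0.05. Fos fell by 1.99 on the log2 scale (SE 0.19, limma adjusted p = 0.00475) and Dusp1 by 0.88 (SE 0.10, limma adjusted p = 0.018), the 3 arrays at 60 min lying below the 3 at 30 min for both. Over all tested probe sets the arrays of the 2 times did not overlap for 11.6%, where chance gives 10% on average over splits. The call of Fos was lost without 30 min replicate b. That of Dusp1 remained only without 60 min replicate b, and was lost in the other 8 fits with 1 array left out, in a fit of these 2 groups alone and without a variance trend. The intensity of Dusp1 at 60 min was 1200 ± 119, 1.90-fold above the start. The falls of Ccn2 and Egr1 from their 30 min level, by 1.08 and 0.75, did not pass, with limma adjusted p of 0.332 and 0.499, and neither did the further rise of Bhlhe40, by 0.80 (limma adjusted p = 0.28). The count was 1 in the 7 fits without a 0 min array, 30 min replicates a or c, or 60 min replicates a or c, 0 in limma without 30 min replicate b, where 1095 had an unadjusted p under 0.05, and 5 without 60 min replicate b. Of the lists, the immediate-early genes were lower (camera adjusted p = 0.0237) and the ribosomal proteins higher (0.000443), both with an adjusted p of 0.411 with an estimated correlation. Adjusted over the list alone, 5 immediate-early genes were lower and 1 higher and 0 ribosomal protein genes changed. The ribosomal median was 0.27 as deposited and 0.07 after quantile normalization, and the immediate-early median -0.13 and -0.15.

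**Figure D4:**
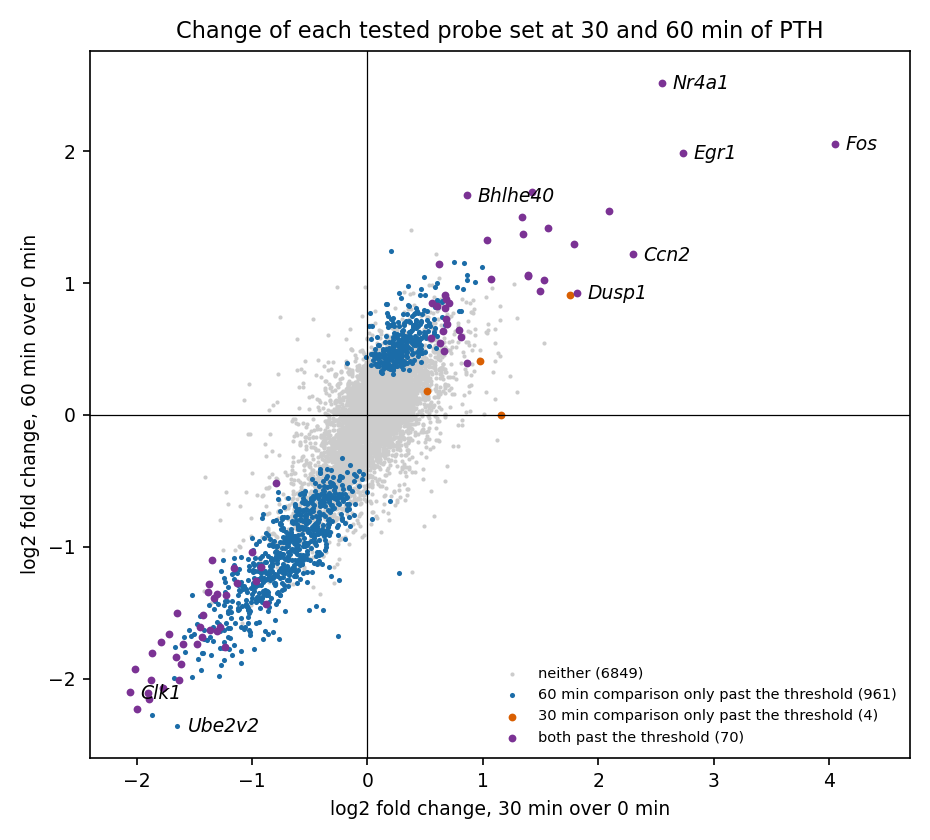
Log2 fold change against 0 min of each of the 7884 tested probe sets at 30 min (horizontal axis) and 60 min (vertical axis), coloured by whether either comparison passed an adjusted p of 0.05. The 70 probe sets past the threshold at both times comprised 34 higher and 36 lower at both, with 0 in opposite directions.

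Over the 3 times 366 probe sets changed by the F test, and 18, 25 and 27 without 0 min replicates a, b and c, 652 and 101 without 30 min replicates a and c, and 659 and 92 without 60 min replicates a and c. Of the 38 rises at 30 min 34 were also called at 60 min, and of the 36 falls 36 were, where independent lists would share 1.65 and 3.14. Because both comparisons use the same 0 min arrays, unchanged groups were simulated against shared controls. They shared 0 rises and 0.02 falls on average, but hold no changed probe sets and so set no level for the overlap among called ones. The 70 shared calls were 14, 15 and 22 without 0 min replicates a, b and c, 284, 22 and 16 without 30 min replicates a, b and c, and 329 and 35 without 60 min replicates b and c. The log2 fold changes at 30 and 60 min had the same sign for 80.0% of probe sets, against 66.6% in the simulation, and correlated across probe sets with r = 0.825, against 0.498. Their covariance was 0.153, against 0.0237. Probe sets are not independent replicates, and the 3 control arrays could not be split into groups of at least 2. The simulation shared the controls but drew noise independently for each probe set. Part of the excess may therefore come from deviations that many probe sets have in common on an array, the shared controls included.

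Several genes known as targets of PTH or cAMP did not pass the threshold at either time. Mmp13, the collagenase of bone, stood at a log2 fold change of -0.66 at 60 min (SE 0.24, limma adjusted p = 0.0883) from an intensity of 3356 ± 354. Fosb stood at -0.12 at 30 min (limma adjusted p = 0.652) and Per1 at 0.37 at 60 min (0.239). From dim probe sets, Ptgs2 stood at 0.71 at 30 min (SE 0.44, limma adjusted p = 0.411), Nr4a2 at 0.64 at 60 min (0.131), and Rgs2 and Pde4b at 0.37 and -0.25 at 30 min. Crem, Il6, Tnfsf11, which encodes RANKL, and the PTH receptor gene Pth1r were too dim to be tested, with mean intensities of 9.90 to 34.5 over the 3 times. No probe set analysed here was named for Nr4a3, Lif, Sik1, Areg, Runx2 or Bglap.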

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

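The tests of the array splits and of handling were chosen before their results were seen.

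Fos and Dusp1 were singled out because their change differed between the PTH times in a direct test of 60 against 30 min. The log2 fold change of 60 over 30 min was -1.99 for Fos and -0.88 for Dusp1. Both rose at 30 min and stood between their 0 and 30 min levels at 60 min. The call of Dusp1 remained in 1 of the 9 fits with 1 array left out and that of Fos in 8.

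The rise of immediate-early genes at 30 min was set against handling of the cultures, since a change of medium also induces Fos and Egr1. The arrays analysed here include 0 of cultures handled without PTH, so handling and PTH cannot be told apart, and the absence of such arrays is what keeps this open. The effect of PTH itself stays the other open explanation.

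Other splits of the arrays into groups of 3 were fitted in the same way. For 30 against 0 min the real split gave 74 probe sets and the highest other split 1, for 60 against 0 min 1031 and 1, and for 60 against 30 min 2 and 1. In each, 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. For the F test 3 of 100 splits of the 9 arrays, the real one included, gave as many as the real 366, a share under 0.05. The 2 others gave 667 and 502 probe sets, and both kept the 3 arrays at 0 min together and mixed those at 30 and 60 min. The share thus argues against chance only for a difference of the 0 min arrays from the rest. It gives no support to the grouping at 30 and 60 min, and cannot tell time from another difference between the arrays.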

How the results depend on the processing

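Cyclic loess and the array score as a covariate were chosen after seeing the data. Of the genes and lists named here, those that passed the threshold kept their direction in the alternatives run on them. Against 74 probe sets at 30 min, 1031 at 60 min, 2 between 30 and 60 min and 366 in the F test, the fit without a filter gave 39, 652, 2 and 158, an adjusted p under 0.01 gave 17, 111, 1 and 25, and the fit without a variance trend gave 40 at 30 min and 184 in the F test. At 30 min a constant 4 times as large gave 115, quantile normalization 145, the 2 groups alone 389 and the array score as a covariate 334. That covariate gave 592 in the F test. A fold of at least 2 gave 396 at 60 min and 1 between 30 and 60 min, where the 2 groups alone also gave 1. Leaving out 1 array gave 16 to 557 at 30 min, 77 to 1584 at 60 min, 0 to 5 between 30 and 60 min and 18 to 659 in the F test. The probe sets called at both times, 70, became 129 after quantile normalization, 38 without a filter and 14 to 329 with 1 array left out. The lists called at 30 min, 5, became 1 with an estimated correlation and stayed at 4 or 5 with 1 array left out. With fry, which does not compare a list with other genes, they became 6. Fry added the matrix protease and NF-kappaB lists (fry adjusted p = 0.011 and 0.0242) and dropped the cell cycle list (fry adjusted p = 0.143). The lists called at 60 min, 4, became 1 with an estimated correlation, 8 with fry, 2 after quantile normalization and 3 to 8 with 1 array left out. Fewer arrays, or more probe sets tested, account for part of the lower counts by construction. The 60 min arrays enter the 30 against 0 min comparison only through the shared estimate of the spread. Its 557 without 60 min replicate b and its 389 with the 2 groups alone therefore came from that estimate, at unchanged fold changes. Thus 74 against 1031 does not by itself show a later onset. Otherwise the cause was not tested.

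With the replicate letter as a block the counts were 259, 1446, 1 and 834, the call of Fos between 30 and 60 min remained and that of Dusp1 was lost, and the cell cycle list at 30 min and the NF-kappaB list at 60 min missed the threshold (adjusted p = 0.121 and 0.0514). Deviations of same-lettered arrays correlated over 0.1 in 2 of 9 pairs, and 4 of 9 arrays correlated best with their own letter, so the letters were not taken as a pairing. Scaling moved the median of all probe sets by at most 0.1 on the log2 scale. Signal over background limits the dim probe sets, for which the added constant compresses the fold.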

Other observations

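The tests of scaling, RNA degradation, single probe sets, shared sequence and of the array axis as the whole cause were chosen after the results were seen, the last because the first test of the axis had left it undecided and in their present form after earlier forms, which counted calls, had been seen, and so were the gene families named by the start of their symbol.

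Among 59 families of genes whose symbols share a start, 2 were enriched in 1 direction at 60 min after adjustment over 118 tests (one-sided Fisher's exact test). Of 66 genes named Zfp, most of which encode zinc finger proteins, 18 fell and 0 rose, against 8.89% of other genes falling (adjusted p = 0.00175), with Zfp62 (-2.01), Zfp982 (-1.89) and Zfp932 (-1.80) falling most, the last 2 on probe sets marked as shared or incomplete. Their median log2 fold change was -0.19, and between -0.15 and -0.10 under the other scalings. Of 13 Dnajc genes, co-chaperones of the Hsp70 system, 6 fell (adjusted p = 0.032). Fisher's test takes genes as independent, whereas many share deviations on an array, so the adjusted p of both families may be too small. The Dnajc excess was not weighed against signal, the array axis or shared sequence. The proteasome subunit genes named Psmd had 4 of 13 members higher, which did not pass (adjusted p = 0.0885).

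If decay is steady and no new transcript is made, a log2 fold change of -2.06 within 30 min needs a level that drops 2-fold every 14.6 min at the slowest for Clk1, and every 18.1 min for Sh3bgrl. Over the 36 probe sets that fell at 30 min the median of this time was 21.0 min, and their median further change from 30 to 60 min was -0.14. Steady decay would have lowered them by as much again in that time, so their course goes against the assumption. For Omd the fall by 60 min needs 31.1 min and for Postn 48.7 min, if spread evenly over the 60 min. Omd already stood at -1.44 at 30 min (SE 0.38, limma adjusted p = 0.101), most of its fall. Transcript stability was not analysed here.

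The 688 probe sets lower at 60 min were weighed against an axis along which arrays of the same time differ, led by 60 min replicate b, on which 96.5% of them loaded negatively (48.3% of all tested) and 85.1% of the risen ones positively, against that array alone and against scaling. The axis cannot be told apart from PTH, in part or as the whole cause. Loadings predicted 44.9% of the median fall of -1.05. With an array score from probe sets without a clear time effect as a covariate, -0.77 was left (SE between arrays 0.25, 544 or 79.1% still passing). On that score 60 min replicate a (-10.5) lay among the 0 min arrays (-11 to -4.9) and replicate c (-4.7) just above them. With the score from all tested probe sets -0.51 was left (SE 0.30, under the bound of 2 SE, 22 still passing where 66 of all tested passed). That score favours the axis and set 60 min replicates a and c (-4.4 and 3.0) above the 0 min arrays (-18.9 to -12.6). Both SE take the spread between arrays from a fit of the times without a score. That spread still holds the axis, so the SE are not those of the covariate fits. Without 60 min replicate b the median fall was 77.8% of its size. The probe sets had been called with all 3 arrays at 60 min, which favours those low on each, so this share decides little. A fit without that array still called 373 falls, which argues, narrowly, against that array as the whole cause. After quantile normalization 86.0% of the probe sets still passed, which argues against the scaling as the whole cause. RNA degradation stays open: the log2 of the 3′ over 5′ signal was higher on every 60 min than on every 0 min array for 0 of 3 control transcripts, but its mean went from -0.95 ± 0.62 to -0.50 ± 0.32 for Actb, from 0.54 ± 0.12 to 0.61 ± 0.16 for Pcx and from -0.38 ± 0.15 to -0.43 ± 0.07 for Gapdh (SD), differences too small against their spread to decide. Loss of signal in single probe sets stays open in part, since other probe sets of the same genes had 56.9% of the fall of the most fallen (64 of 173 also passed as lower and 0 as higher), and so do a response to PTH and the missing time-matched control.

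The excess of Zfp genes among the fallen genes at 60 min was weighed against low signal, the same array axis and shared sequence. The count of 18 lay above 100% of 10000 random lists matched on mean signal, which argues against low signal as the whole cause. Among probe sets without a suffix letter, which marks shared or incomplete probes, the 12 of 55 that fell lay at the 99.3 percentile, just over the bound of 99. The family was chosen from 59 for its excess in these same calls, which raises both percentiles. The narrow margin of the second therefore cannot decide on shared sequence. Of the 11 with such a letter 6 fell, and shared sequence stays open. The median loading of the Zfp genes on the array axis lay at percentile 1.49 of the matched lists, consistent with a contribution of the axis. With an array score as a covariate, the 540 lowest genes, as many as had fallen, held 17 Zfp genes under the first score and 18 under that from all tested probe sets. Both lay at percentile 99.99. By calls, 16 of 66 Zfp genes still passed as lower under the first score (percentile 99.99) but 0 under the second (percentile 0), where few genes of any kind passed. The median of the fallen Zfp genes went from -1.46 to -1.23 and -0.98. The ranking takes 540 genes however small their change, so it cannot exclude the axis. The axis as the whole cause and a response of these genes to PTH both stay open.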
